A study of Arabidopsis thaliana with 6 samples.

How the data were processed

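JAGGED (JAG), a C2H2 zinc finger protein that promotes the growth of lateral organs in Arabidopsis thaliana, was immunoprecipitated with its DNA through a green fluorescent protein (GFP) tag. Per the labels' protocols, plants carrying a genomic JAG-GFP fusion in the jag-2 mutant were compared with wild-type Landsberg erecta plants, which lack the tag and so give the background of the antibody. Plants were grown with 16 h of light and 8 h of dark, at 18 °C by day and 20 °C by night and 80% humidity. Inflorescence apices with unopened buds, 1300 to 1500 mg per sample, were fixed with formaldehyde, sonicated to fragments of about 500 bp and precipitated with anti-GFP beads. There were 3 JAG-GFP and 3 wild-type samples, grouped by their titles. The labels number the replicates but do not say whether they came from separate sets of plants, so the spread between lists, and any p-value that rests on it, may be technical.

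The files analysed here were 3 peak lists, 1 per replicate number. Per the file headers, each peak had a chromosome, start, end, width, the position of its maximum (the summit) and a score deposited by the authors. The score of a peak is the authors' own value, and its scale, the peak caller and the threshold are not given in the sources used here, although the word ratio in the name of each list points to a comparison with a control. It was used to rank peaks within a list. It was also averaged over lists, as mean ± SD, which assumes a scale common to the lists that is not known. Whether each list was made against its own wild-type sample or against a common one is also not given. Base calling with CASAVA 1.8 and the genome build TAIR10 are named in the submitters' processing notes. Coordinates are printed as in the lists, on TAIR10. Read counts and depth per library were not analysed here, so no detection limit could be computed, and intervals given for shares cover counting error only. The number of peaks per list limits the precision: a share of 869 regions has a 95% Wilson interval of about 3 percentage points on either side.

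The 3 lists were compared by merging all peaks that overlapped by at least 1 bp. A merged region was called shared if it held a peak of each list. Its summit was the median of the summits of the highest peak from each list. The list of replicate 3 held no peak on chromosome 1 past position 23827070. Peaks and genes past that position could not be in all 3 lists and were left out of the shared set, its random expectation and the gene background. Random expectation for sharing came from 1000 relocations of the peaks of 2 lists within their chromosome (200 for the rules with an overlap of 50% and with 2 of 3 lists). For positions relative to genes, the summits of the shared regions were themselves relocated 1000 times. The smallest p these can give is 0.001 one-sided, 0.002 two-sided and 0.005 with 200 relocations. Scores of shared and single-list peaks were compared by a two-sided permutation test of the difference in median score percentile with 100000 draws, for which 1e-05 is the smallest p. Peaks and regions are not biological replicates, so these tests describe the lists.

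Gene names and neighbours came from the RefSeq gene table of assembly TAIR10.1, and no coordinate of that table is printed. That table has no strand, so the planned window of 3000 bp upstream to 1000 bp downstream of a gene was replaced by 3000 bp on both sides, and the planned promoter share by the share of summits outside genes and within 1000 bp of one. No genome sequence was used, so the planned count of sequence words was not made. Of 27444 nuclear protein-coding genes, 25680 remained after the end of chromosome 1 was left out. Gene lists were compared with all other tested genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 15 lists at a false discovery rate of 0.05. The test treats genes as independent, although neighbouring genes can share a region. The lists held 255 loci, all found in the gene table, of which 234 could be tested. They covered cell cycle inhibitors, D-type cyclins, other core cell cycle genes, floral meristem and organ identity, organ boundary, shoot meristem, organ polarity, organ growth, auxin, gibberellin, cytokinin, chromatin and co-repressors, photosynthesis, seed storage, and highly transcribed housekeeping genes. The last 3 lists served as markers of leaf tissue, of genes silent in buds and of strongly transcribed chromatin.

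The groups, tests, gene lists and alternatives were fixed before the data were examined, except where stated. The gene background was corrected after results had been seen. It had ended chromosomes 2 to 5 at their last peak, and 29 genes past those ends were added. Organ growth went from 9 of 30 (odds ratio 6.47, adjusted p = 0.00091) to 9 of 31 (6.18, adjusted p = 0.0012; both Fisher's exact test). With relocation within the chromosome, organ polarity went from an adjusted p of 0.0450 to 0.0749 (permutation test) and no longer passed. The same 5 lists passed Fisher's exact test before and after. Named genes followed a rule: the genes nearest to the 15 regions with the best mean rank of score, up to 5 members of each gene list with a shared region in order of rank, and JAG, KRP2, KRP4 and PTL whatever their values. Other genes beside a named region, at the end of chromosome 1 or in the families screened by symbol were named after their values were seen. Alternatives were the 50% of each list with the highest scores, an overlap of 50% of both peaks, summits within 200 bp, 2 of 3 lists, leaving out each list, other windows, the nearest gene only, relocation in place of Fisher's exact test, and a logistic model with the length around a gene that is free of other genes. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used. The procedure was tested on simulated data, in 20 sets of 3 lists of the used sizes with 600 planted common sites. On average 99.95% of the planted sites were recovered, a list of 30 genes with 9 planted members passed an unadjusted p of 0.05 in 20 of 20 sets, and a random list of 30 did so in 0 of 20. Sites were planted at the members themselves and the other peaks were placed at random, so this checks the code. It does not measure false calls from gene spacing or from clustered regions.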

Results

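Chromatin immunoprecipitation followed by sequencing was used to find where JAG binds in the genome of floral buds. The study had 3 JAG-GFP and 3 wild-type samples. Peaks were listed for 3 replicates, with 2620 peaks for replicate 1, 2143 for replicate 2 and 2127 for replicate 3. Median peak width was 1032.5 bp, 982 bp and 976 bp in the same order, and the peaks covered 3194 kb, 2424 kb and 2411 kb. The authors' scores began at 1.86, 1.89 and 1.87, with medians of 2.04, 2.08 and 2.12.

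The tagged gene itself was examined first. Over the JAG locus (AT1G68480), the list of replicate 1 had a peak on chromosome 1 from 25682653 to 25692819 with a score of 14.54, and that of replicate 2 a peak from 25680784 to 25692817 with a score of 16.96. These were the highest scores of both lists. The next highest were 7.84 and 7.42. The peaks were also the widest, at 10167 bp and 12034 bp. The widest of all other peaks had 6442 bp and 5268 bp, and the 20 peaks that followed by score had medians of 1407.5 bp and 1253.5 bp. The list of replicate 1 held another peak beside it (25679864 to 25681692, score 2.42), and the peak of replicate 2 overlapped both. The locus lies past the last chromosome 1 peak of replicate 3 and could not be examined in that list. The transgene carries a genomic copy of JAG that the wild-type control lacks, so a peak here does not by itself measure binding.

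**Figure D1:**
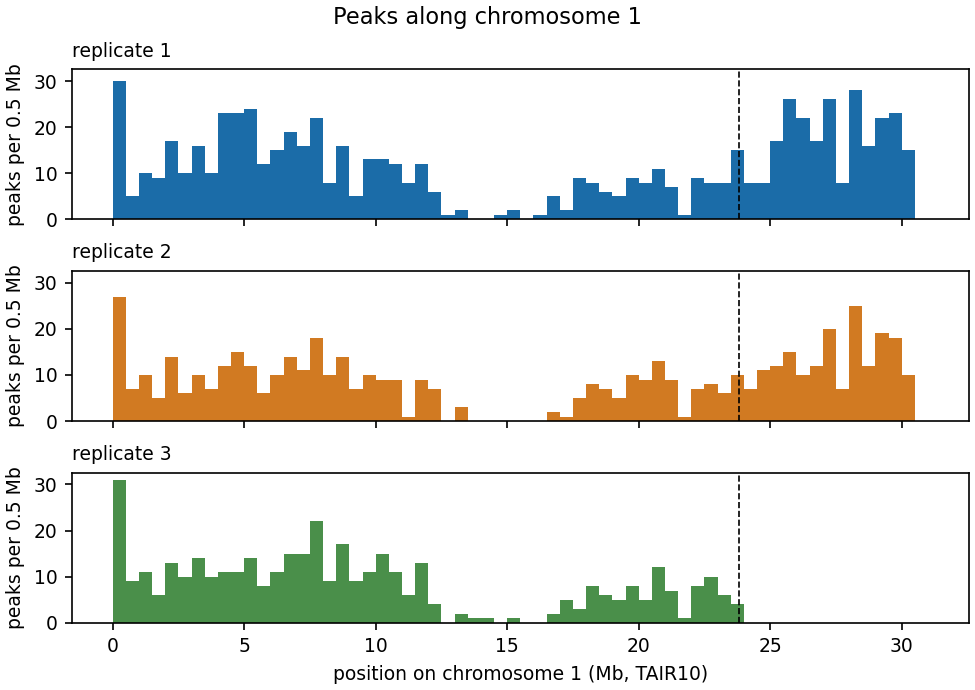
Peaks per 0.5 Mb (vertical axis) along chromosome 1 (horizontal axis, Mb on TAIR10) in the lists of replicates 1, 2 and 3, with a dashed line at position 23827070. The list of replicate 3 has 0 peaks past that line, where replicates 1 and 2 have 244 and 183.

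The first comparison asked which sites recurred across the replicates. Among the highest-scoring recurrent sites were both KRP4 and KRP2, which encode inhibitors of cyclin-dependent kinases. The region over KRP4 (AT2G32710, chromosome 2, 13875119 to 13877319) scored 7.44, 7.22 and 9.07 in the lists of replicates 1, 2 and 3 and ranked 2nd of all shared regions. Its summit lay in the gene body, which at that position is also annotated as CB5-B. The region near KRP2 (AT3G50630, chromosome 3, 18801965 to 18804013) scored 5.59, 5.70 and 6.39 and ranked 6th. It lay outside the gene within 3000 bp, with AT3G50640 as its nearest gene, and another shared region lay within 3000 bp of KRP2.

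**Figure D2:**
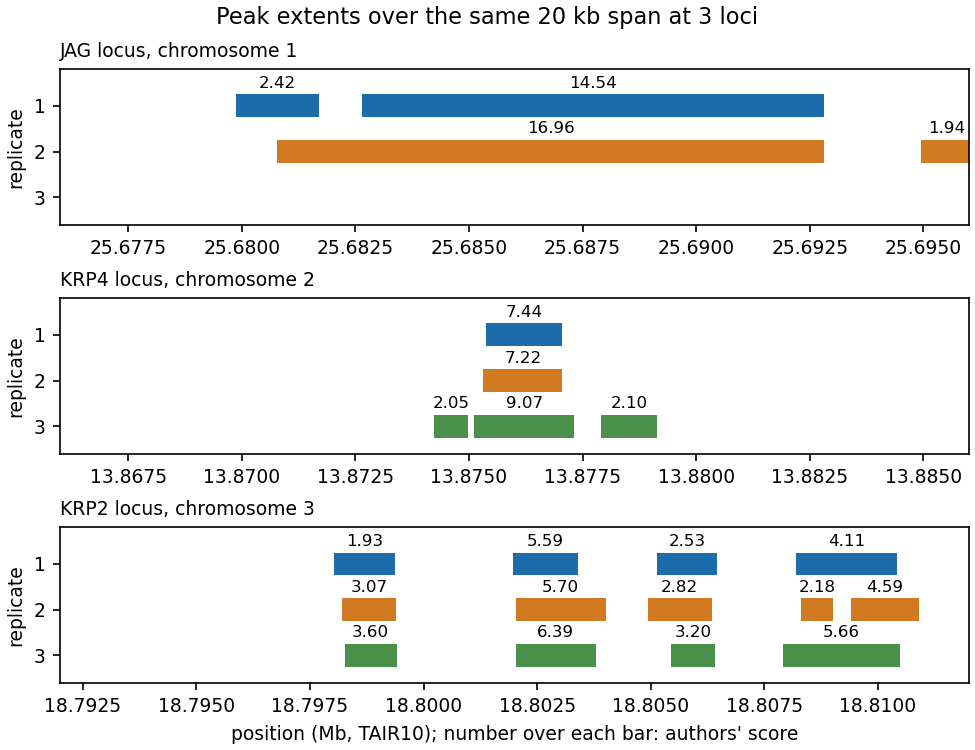
Peak extents (horizontal axis, position in Mb on TAIR10) in the lists of replicates 1, 2 and 3 (rows) over spans of equal length at JAG, KRP4 and KRP2, with the authors' score printed over each bar. At JAG the peaks of replicates 1 and 2 are 10167 and 12034 bp wide and the list of replicate 3 has no peak on that part of the chromosome. At KRP4 and KRP2 all 3 lists show a peak at the same place.

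The 3rd region (chromosome 4, 13657755 to 13660176, scores 6.48, 6.53 and 8.32) had WES1 (AT4G27260), an enzyme that conjugates auxin to amino acids, as its nearest gene. The 4th (chromosome 2, 12259149 to 12260058, scores 6.60, 5.02 and 7.29) lay near PRS (AT2G28610), a homeobox gene of lateral organ margins. The 8th (chromosome 2, 9577008 to 9578763, scores 4.37, 5.28 and 6.86) had its summit in AT2G22530 and lay within 3000 bp of SVP (AT2G22540), a MADS-box repressor of flowering. The 9th (chromosome 2, 12076413 to 12077763, scores 5.42, 4.94 and 6.11) lay farther than 3000 bp from any protein-coding gene, with the chromatin remodeller SYD (AT2G28290) nearest. The highest region of all (chromosome 5, 16236441 to 16238192, scores 7.84, 7.42 and 8.77) had its summit in AT5G40540. The nearest genes of the other top 15 regions were AT1G23390, UNE7, AT1G29630, RLK (AT5G67280), AGK2, AT3G50650, AT3G23170 and AT5G60980, with mean scores from 4.79 ± 0.79 to 6.16 ± 0.70 (SD, n = 3 lists).

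The 3 lists merged into 3683 regions, of which 869 (23.6%) held a peak of every list. Random relocation of 2 of the lists within their chromosomes gave 6.57 ± 2.50 such regions (SD over 1000 draws, highest 16; permutation test, one-sided, p = 0.001, the smallest possible). Regions of 2 lists numbered 196 for replicates 1 and 2, 334 for replicates 1 and 3, and 281 for replicates 2 and 3. Regions of a single list numbered 906, 530 and 567. Whether the lists share a wild-type control is not given in the sources used here, so part of the sharing may come from a common control.

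**Figure D3:**
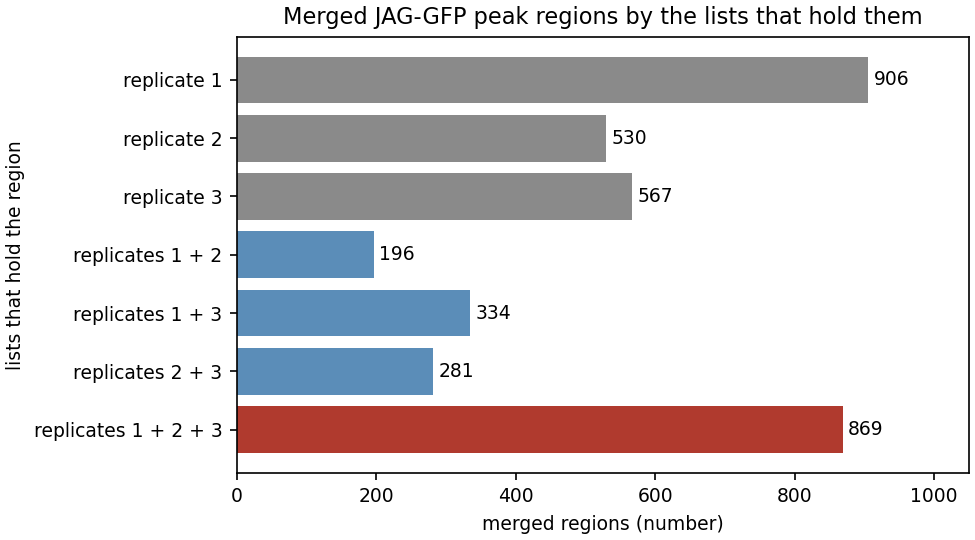
Number of merged regions (horizontal axis) by the lists that hold them (vertical axis), for the part of the genome where all 3 lists have peaks. The bar for all 3 lists reaches 869 regions, against a mean of 6.57 after random relocation.

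Recurrence rose with the score of the peak. Of the 100 highest-scoring peaks used from each list, 99 in replicate 1, 99 in replicate 2 and 100 in replicate 3 were in all 3 lists, and of the 100 lowest 13, 15 and 14 were. Peaks of shared regions had a median score of 2.26, 2.29 and 2.49 in replicates 1, 2 and 3, against 1.94, 1.94 and 1.97 for single-list peaks. The medians differed by 43.4, 49.3 and 48.8 percentiles of the list (permutation test, two-sided, p = 1e-05 in each list, the smallest possible). Across shared regions, which are not independent replicates, the scores of 2 lists correlated with Spearman's rho of 0.55 for replicates 1 and 2, 0.58 for replicates 1 and 3, and 0.68 for replicates 2 and 3. Summits of the same region lay a median of 82, 71 and 52 bp apart in those pairs.

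The second comparison placed the shared regions relative to genes. Summits lay mostly between genes: 411 of 869 (47.3%, 95% Wilson interval 44.0 to 50.6%) were outside protein-coding genes and within 1000 bp of one, against 20.2% ± 1.35 after random relocation (SD over 1000 draws; permutation test, two-sided, p = 0.002, the smallest possible). Gene bodies held 230 summits (26.5%, 23.6 to 29.5%), against 53.5% ± 1.69 at random (p = 0.002 in the same permutation test). Only 34 summits (3.91%, 2.81 to 5.42%) were farther than 3000 bp from a gene, against 15.1% at random, but against 2.96% when regions were moved by 100 to 500 kb, from which they did not differ by the test (permutation test, two-sided, p = 0.114). With those moves gene bodies held 65.3%, and places outside and within 1000 bp held 22.2%. Farther than 1000 bp lay 26.2% of summits, against 12.5% with those moves (permutation test, two-sided, p = 0.002). Relocation within the whole chromosome gave 26.3%, so no excess was seen there. Against the moves of 100 to 500 kb, sites outside genes were thus in excess on both sides of 1000 bp. Because these comparisons differ, the excess within 1000 bp does not by itself show closeness to genes. Pseudogenes, which are dense near centromeres, had a shared summit within 1000 bp in 7 of 3897 cases. That was below the 29.3 ± 5.22 found with the same moves (permutation test, two-sided, p = 0.002). These moves were chosen after the data were examined. The share of upstream against downstream sites was not analysed here because the gene table has no strand.

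The third comparison asked which groups of genes lie near shared regions, and 1602 of 25680 tested genes (6.24%) had a summit in the gene or within 3000 bp. Random relocation gave 1605 ± 34.3 genes (SD over 1000 draws). Of the organ growth genes, 9 of 31 (29.0%) had a region, an odds ratio of 6.18 (95% interval 2.50 to 14.0; Fisher's exact test, two-sided, adjusted p = 0.0012). The 5 with the best ranks were GRF5 and GRF8, which encode growth-regulating transcription factors, GIF1 (AT5G28640), their co-activator, and TCP4 and TCP14, members of a family that controls cell proliferation. GIF1 scored 3.40, 3.66 and 4.16 in replicates 1, 2 and 3 over its gene body (chromosome 5, 10648309 to 10649228). GRF5 (AT3G13960, chromosome 3, 4605774 to 4608884) scored 3.09, 2.85 and 2.93. TCP4, TCP14 and GRF8 had mean scores of 2.40 ± 0.11, 2.42 ± 0.31 and 2.66 ± 0.58 (SD, n = 3 lists). Of the settings tried, 2 chosen after the data were examined ended the organ growth call: a window of 500 bp (3 of 31, odds ratio 4.72; Fisher's exact test, adjusted p = 0.0821) and relocation by 100 to 500 kb (observed over expected 3.24; permutation test, adjusted p = 0.0599).

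Organ polarity genes had a region in 5 of 14 cases (odds ratio 8.37, 2.201 to 27.9; Fisher's exact test, adjusted p = 0.0088). They included ETT and PHB, which act on the lower and upper organ side respectively, and KAN1, KAN2 and AS1, with mean scores between 2.03 ± 0.12 and 2.31 ± 0.51 (SD, n = 3 lists). The polarity call ended with the highest-scoring 50% of each list (odds ratio 4.53, adjusted p = 0.162) and with a window of 1000 bp (8.25, adjusted p = 0.0674; both Fisher's exact test). It also ended with relocation within the chromosome (observed over expected 5.01; permutation test, adjusted p = 0.0749) and in the logistic model (odds ratio 5.49, adjusted p = 0.0516). The 2 settings that ended the organ growth call gave 1 of 14 and 3.38 at 500 bp (Fisher's exact test, adjusted p = 0.369), and an observed over expected of 3.41 with the moves (permutation test, adjusted p = 0.180). Floral meristem and organ identity genes had a region in 5 of 19 cases (odds ratio 5.38, 1.51 to 15.8; Fisher's exact test, adjusted p = 0.026). AP2, which specifies sepals and petals, scored 2.42, 2.87 and 3.45 in replicates 1, 2 and 3 within 3000 bp (chromosome 4, 17404485 to 17405770). SEP3 and LFY had summits in their gene bodies, with mean scores of 2.76 ± 0.39 and 2.40 ± 0.05 (SD, n = 3 lists). FUL and SHP1 reached 2.99 ± 0.68 and 2.06 ± 0.26 on the same measure. Leaving out replicate 3 as planned also puts the end of chromosome 1 back, so it was repeated with that end still left out, a setting added after the data were examined. The floral list then had an odds ratio of 4.21 (Fisher's exact test, adjusted p = 0.0505), against 3.82 as planned (adjusted p = 0.0702 in the same test).

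Auxin genes had a region in 4 of 16 cases (odds ratio 5.02, 1.18 to 16.6; Fisher's exact test, adjusted p = 0.046), namely the kinase gene PID, the auxin exporter gene PIN7, and the response factor genes ARF2 and ARF8. PID scored 2.26, 2.97 and 3.65 in replicates 1, 2 and 3, and ARF2 scored 2.02, 2.11 and 1.9. PIN7 and ARF8 had mean scores of 2.42 ± 0.36 and 2.49 ± 0.42 (SD, n = 3 lists). Another gene was nearer to the summit at ARF2. That gene had no region without replicate 1, without replicate 3 or at 1000 bp, but kept one without replicate 2 and with 2 of 3 lists. D-type cyclins, which promote entry into the cell cycle, had a region in 3 of 9 cases, near CYCD3;2, CYCD3;3 and CYCD4;1 (odds ratio 7.53, 1.22 to 35.3; Fisher's exact test, adjusted p = 0.046). Mean scores at CYCD3;3 and CYCD4;1 were 2.58 ± 0.40 and 2.41 ± 0.14 (SD, n = 3 lists), but another gene was nearer to the summit at CYCD4;1. Without replicate 3 auxin genes had 3 of 16 and an odds ratio of 2.72 with the end of chromosome 1 left out (Fisher's exact test, adjusted p = 0.234), and 3 of 19 and 2.14 with it put back (adjusted p = 0.322). D-type cyclins did not pass without replicate 1, 2 or 3, with odds ratios of 5.57, 5.31 and 5.89 over 9 genes (Fisher's exact test, adjusted p = 0.0690, 0.0677 and 0.0844), or 4.90 over 10 genes without replicate 3 and with that end put back (adjusted p = 0.122). Keeping the genes of that end with all 3 lists by itself ended both calls, at 4.31 for auxin and 6.92 for D-type cyclins (Fisher's exact test, adjusted p = 0.0665 and 0.0655).

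The other lists did not pass the adjusted threshold. Cell cycle inhibitors had a region in 3 of 16 cases, KRP2, KRP4 and KRP7 (odds ratio 3.47, 0.63 to 12.7; Fisher's exact test, adjusted p = 0.14; without replicates 1 and 2 in turn 5 of 16, adjusted p = 0.0229 and 0.0230, and 3 of 16 without replicate 3, odds ratio 2.72 and adjusted p = 0.234 with the end of chromosome 1 left out, 2.64 and 0.249 with it put back), and KRP7 scored 2.58, 2.38 and 3.00. The rest of the core cell cycle list, cyclins A and B, their kinases and the E2F factors, had 0 of 20, against 1.25 expected (interval of the odds ratio up to 3.05). Boundary genes had 3 of 11 (odds ratio 5.64; Fisher's exact test, adjusted p = 0.068), and 4 of 11 without replicate 1 or without replicate 2 (adjusted p = 0.0237 in both). Without replicate 3 they had 3 of 11 with the end of chromosome 1 left out and 3 of 12 with it put back (odds ratios 4.42 and 3.81; Fisher's exact test, adjusted p = 0.123 and 0.165), and at 1000 bp 0 of 11. BOP1, a co-activator of the organ boundary, had a mean score of 4.57 ± 0.76 (SD, n = 3 lists; chromosome 3, 21144255 to 21145426, 16th of all regions). PTL (AT5G03680), a trihelix factor that limits growth between sepals, scored 2.33, 3.15 and 3.82 (chromosome 5, 961786 to 962535), but another gene was nearer to that summit. BOP2 had a mean score of 2.50 ± 0.58 (SD, n = 3 lists). Gibberellin genes had 3 of 12 (odds ratio 5.02; Fisher's exact test, adjusted p = 0.075; without replicate 1 odds ratio 3.71, adjusted p = 0.131, without replicate 2 7.59, adjusted p = 0.0067, and without replicate 3 adjusted p = 0.0505 with the end of chromosome 1 left out and 0.0272 with it put back), the biosynthetic gene GA20OX2 and the growth repressors RGA and RGL2, with mean scores of 3.10 ± 0.60, 2.38 ± 0.26 and 2.35 ± 0.21. Shoot meristem genes had 2 of 13 (PNY and ATH1), chromatin and co-repressor genes 2 of 20 (TPL and TPR3) and cytokinin genes 1 of 12 (ARR7). The comparison lists did not pass either, with 1 of 21 photosynthesis genes (LHCA2), 1 of 8 seed storage genes (CRU3) and 1 of 12 housekeeping genes (EF1A-A4), and odds ratios of 0.75, 2.15 and 1.37.

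**Figure D4:**
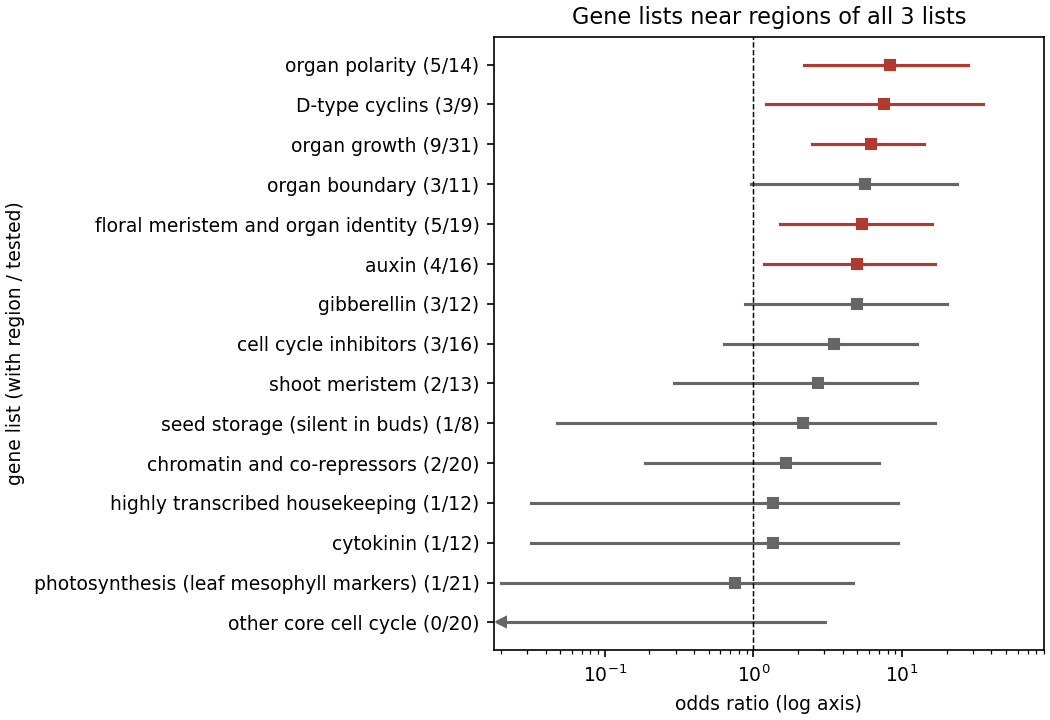
Odds ratio of having a shared region in the gene or within 3000 bp (horizontal log axis) for each gene list (vertical axis, with members having a region over members tested). Squares are estimates, lines 95% intervals, red marks an adjusted p under 0.05 and the arrow an estimate of 0. Organ growth has the narrowest interval of the lists in red, 2.50 to 14.0.

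Which lists passed varied with the setting. The organ growth list passed in 11 of 13 other settings, organ polarity in 7, floral identity in 6, auxin in 5 and D-type cyclins in 0. A window of 1000 bp, relocation within the chromosome and the logistic model each ended the floral identity, auxin and D-type calls (adjusted p from 0.0674 to 0.160 in Fisher's exact, permutation and likelihood ratio tests). Their odds ratios were 5.67, 6.98 and 8.64 at 1000 bp, where 3 of 19, 3 of 16 and 2 of 9 genes had a region, and 4.11, 3.43 and 5.97 in the logistic model. With relocation the observed over expected was 3.83, 3.83 and 5.42. Cell cycle inhibitors and gibberellin genes each passed in 5 of the 13 and boundary genes in 3. The median length free of other genes, gene included, was 6142 bp for organ growth, 7513.5 bp for organ polarity and 5005.5 bp for housekeeping genes.

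**Figure D5:**
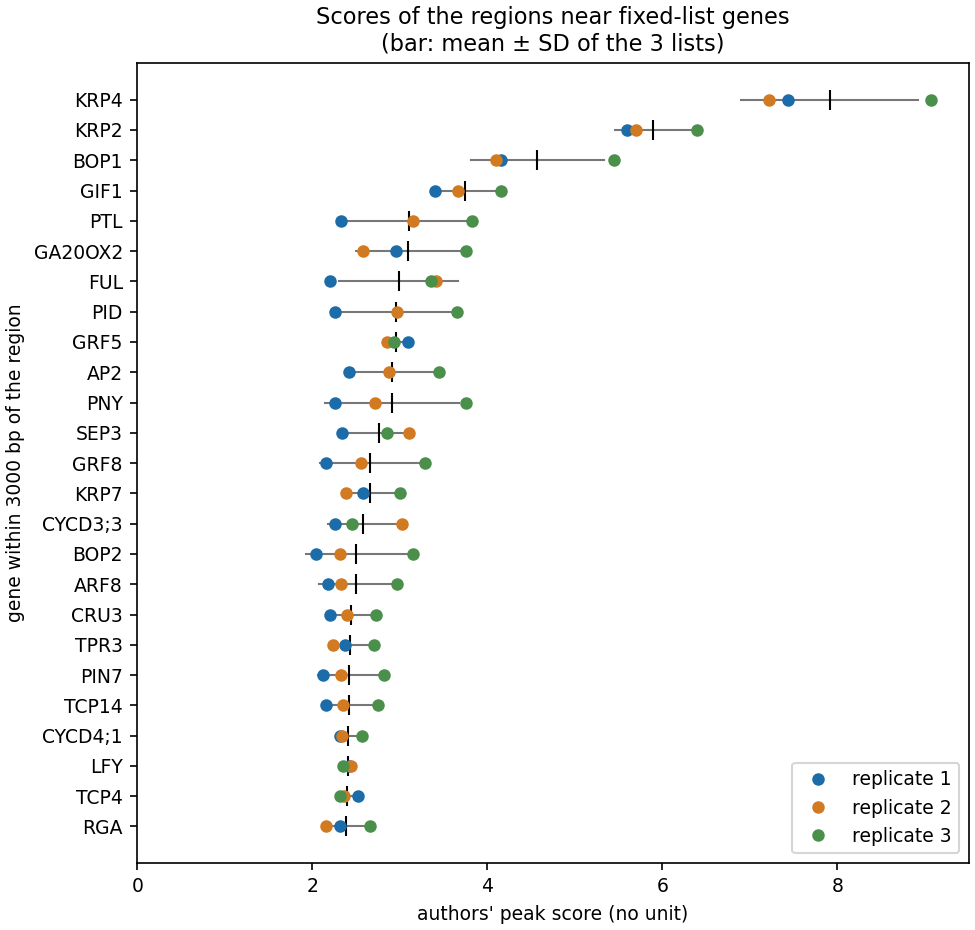
Authors' peak score (horizontal axis, no unit) of the shared region near the 25 highest-scoring genes of the fixed lists (vertical axis), with a dot per replicate list, a tick at the mean and a line for ± 1 SD. KRP4 and KRP2 lie apart from the other list genes, with all scores above 5.5.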

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

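The tests on the end of chromosome 1 and on the JAG peak, and the use of the housekeeping and photosynthesis lists as a test of transcription, were chosen after the results were seen, whereas the gene list tests and the logistic model were planned.

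The lists of replicates 1 and 2 hold 244 and 183 peaks on chromosome 1 past position 23827070, where the list of replicate 3 ends. These peaks entered no comparison of all 3 lists. They form 114 regions common to replicates 1 and 2. Weak peaks lost by chance are argued against, because 81.8% of such regions recurred in replicate 3 elsewhere, which predicts 93.2 here, and the longest run of neighbouring regions missing elsewhere was 3, against all 114 here. A list that does not cover this stretch stays open and cannot be told apart from other causes, since the stretch was set by the last peak of that list. Elsewhere, 100% of the 110 regions with mean scores in the upper 10% were found in replicate 3. No biological explanation was tested. After JAG, the best of the 114 regions had AT1G76170 nearest (28582609 to 28583952, scores 6.82 and 6.37 in replicates 1 and 2). Of the 21 fixed-list genes here, 4 had a region within 3000 bp: JAG, the cytokinin response gene ARR15, the meristem receptor gene CLV1 and the gibberellin-inactivating gene GA2OX1.

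The peak over JAG, with scores of 14.54 in replicate 1 and 16.96 in replicate 2, lies in that stretch and likewise entered no comparison of the 3 lists. Whether a single binding site could give the whole width in these 2 lists cannot be told here. Fragments were about 500 bp, whereas the peak was 10167 and 12034 bp wide, and the widest of all other peaks had 6442 and 5268 bp. The width was at least 3.91 times that of the widest of the next 20 peaks by score in both lists. The peak was picked out for its width, so that ratio is not a test by itself. The next scores were 7.84 and 7.42, so no other peak of these lists matches it in score. Extra copies of the JAG fragment carried by the transgene are a candidate explanation: the right ends of the peak differed by 2 bp between the lists, and 1.36% of 2204 peak ends common to both lists were as close. The left ends differed by 1869 bp, or by 920 bp if the smaller neighbouring peak of replicate 1 is joined (median of all ends 183 bp). Of all common ends, 99.2% were as close as the left ends, or 93.1% if joined, so a fixed edge is seen on 1 side only. The closer of the 2 ends was taken, so 1.36% is lower than the share for either end would be. Binding of JAG at 1 or several sites in its own gene, with or without extra copies, stays open, since per-library coverage was not analysed here.

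Shared regions lay near organ growth and polarity genes more often than near other genes. Long surroundings free of other genes are argued against as the whole cause for organ growth, since its odds ratio was 4.82 (2.21 to 10.5, adjusted p = 0.0080) in the logistic model that includes that length, against 6.18 in Fisher's exact test. Adjusted p for this list ranged from 5.7e-06 to 0.0821 over the 13 alternatives (Fisher's exact, permutation and logistic tests). For organ polarity the same model gave 5.49 (1.83 to 16.5), against 8.37 in Fisher's exact test, with an adjusted p of 0.052 (0.00040 to 0.369 over the alternatives). The call was lost but the interval stayed above 1, so that length is not shown to account for the association. Whether that length accounts for part of the association cannot be told here. A general pull-down of strongly transcribed genes cannot be told apart here: the housekeeping list had an odds ratio of 1.37, but 12 genes leave an interval of 0.032 to 9.41, which includes the estimate for organ growth. The photosynthesis list had 0.75 (0.018 to 4.70), with its upper limit below the organ growth estimate of 6.18 but inside the interval of that list (2.50 to 14.0). A biological preference of JAG for growth regulators remains open as well.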

How the results depend on the processing

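Settings with relocation by 100 to 500 kb, a window of 500 bp, the end of chromosome 1 kept among the genes, or that end left out when replicate 3 is left out were chosen after seeing the data, as was the correction of the gene background. No paired analysis was possible because no value per library was analysed. The sequence words were not run, as no genome was at hand. Taking the 50% of each list with the highest scores left 1310, 1072 and 1064 peaks for replicates 1, 2 and 3 by construction. Shared regions numbered 491 with those peaks, 576 with an overlap of 50% of both peaks and 1680 with 2 of 3 lists, all above every random draw, and these differences follow from stricter or looser rules. With 1 list left out, 1166 to 1212 regions were common to the other 2 (1190 without replicate 3, of which 114 lie past the end of its list). Shared peaks outscored single-list peaks also with those 50% and with summits within 200 bp. The share of summits outside genes and within 1000 bp stayed above random in the settings run (47.1 to 48.5% with 1 list left out). The number of gene lists passing was 5 and depended more on the setting. It was 1 with a window of 1000 bp (organ growth), 1 with relocation within the chromosome (organ growth), 1 in the logistic model (organ growth), and 3 with the chromosome end kept. It was 0 with a window of 500 bp and 0 with relocation by 100 to 500 kb, where 7 and 3 lists had an unadjusted p under 0.05 (Fisher's exact and permutation tests). At 500 bp fewer genes had a region, but the odds ratios of floral identity (8.27), auxin (10.2) and D-type cyclins (12.6) were higher than at 3000 bp (5.38, 5.02 and 7.53). Those of organ growth (4.72) and polarity (3.38) were lower, and with relocation by 100 to 500 kb the observed over expected of the 5 lists was 2.80 to 3.44. With 1 list left out it was 3 to 7. The 3 came without replicate 3, which also puts the end of chromosome 1 back: floral identity (odds ratio 3.82), auxin (2.14) and D-type cyclins (4.90) no longer passed and gibberellin (6.36) did. With that end still left out it was 2 (organ growth and polarity), and gibberellin had 5.89. Cell cycle inhibitors passed with the highest 50% (6.28), 2 of 3 lists (5.70), the nearest gene only (6.96) and without replicate 1 (5.07) or 2 (4.83). Over the 13 settings, the calls of the 5 lists were kept in 29 of 65 cases and lost in 36, and other lists passed in 13 cases, with 0 reversed. The cause was not tested. What depth limits could not be examined, since the depth is unknown. Of 52 named genes, 35 kept a region at 1000 bp, where KRP2, BOP1, BOP2 and PTL were among those lost. With the highest-scoring 50% of each list 41 did, and with the nearest gene only 47. An overlap of 50% of both peaks and summits within 200 bp each left 40. All 52 did with 2 of 3 lists, which holds by construction, since that set includes every region of all 3 lists.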

Other observations

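The families below were screened after the data were examined, by the symbol of the gene, with 124 families of at least 12 members tested, of which 8 had an adjusted p under 0.05 (SPL, ERF, PIP, GRF, HB, TCP, SAUR and OFP symbols). The SBP-box family, transcription factors of phase change and flowering, had a shared region within 3000 bp in 8 of 15 members: SPL1, SPL3, SPL4, SPL5, SPL8, SPL9, SPL10 and SPL11 (odds ratio 17.3, 5.46 to 56.0; Fisher's exact test, unadjusted p = 9.8e-07). In the screen by symbol, which counted 16 members, the adjusted p was 0.00023. With the length of the surroundings free of other genes in a logistic model, the odds ratio was 15.3. SPL11 had 3 regions within 3000 bp, a number reached by only 1 other of the 25680 tested genes, ZFP8, and the best of its regions scored 2.94 ± 0.22 (SD, n = 3 lists; chromosome 1, 9501148 to 9502318). SPL10 and SPL11 are neighbours and share a region, so they are not independent.

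Growth-regulating factors had a region in 5 of 9 members (GRF4, GRF5, GRF6, GRF8 and GRF9; odds ratio 18.8), 4 of which were in the organ growth list, so this is not separate evidence. The 14-3-3 genes, which share the GRF symbol, had 1 of 10. Genes with PIP symbols had 6 of 18 in the screen (Fisher's exact test, adjusted p = 0.0233). The 6 were all among the 13 plasma membrane aquaporins, a group formed after the screen, led by PIP1B with a mean score of 3.24 ± 0.37 (SD, n = 3 lists). Genes with ERF symbols, factors of the ethylene response, had 8 of 24, and ERF13 led with 3.53 ± 0.43. That region had its summit in AT2G44830, with ERF13 within 3000 bp. ERF11 and ERF12 are neighbours, so they may not be independent. Genes with SAUR symbols, small auxin-induced genes, had 5 of 16, but SAUR26, SAUR27 and SAUR28 share the same 2 regions. IAA13 had a region that ranked 20th, at 4.44 ± 0.38. Long non-coding RNA genes had a summit within 1000 bp in 132 of 3247 cases, against 72.1 ± 9.24 when regions were moved by 100 to 500 kb (permutation test, two-sided, p = 0.002). For microRNA genes the count was 9 of 303, against 5.12 ± 2.29 (p = 0.16 in the same permutation test). These moves put 65.3% of summits in protein-coding gene bodies, against 26.5% observed. Neither comparison is therefore matched for placement outside protein-coding genes.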
